A study of Rattus norvegicus with 48 samples.

How the data were processed

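Transcript levels were measured in brain cortex and liver of male Sprague-Dawley rats that received RDX, a nitramine explosive, as a single oral dose of 3 or 18 mg/kg. Tissue was collected at 0, 4, 24 and 48 h. Every combination of tissue, dose and time had 3 arrays, which made 16 groups and 48 arrays. Groups were taken from the sample labels. The labels give no vehicle arm at 4, 24 or 48 h, so the 0 h group of the same dose and tissue served as the control. They do not say whether arrays with the same number came from the same animal, whether the 3 arrays of a group came from 3 animals, or at what clock time tissue was taken. The p-values therefore measure only the spread between arrays.

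The authors hybridised biotin-labelled RNA to Affymetrix whole-genome rat arrays and deposited log2 values; the submitters' processing notes name RMA and Partek without a version or settings. RMA corrects background, makes the arrays' distributions alike and summarises the probes of each probe set, so a change shared by most transcripts would be reduced before the values were deposited. Array means lay between 6.737 and 6.741, and array medians between 6.071 and 6.499. The deposited values were used without further scaling. Of 31099 probe sets, 57 hybridisation and degradation controls were left out and 31042 were tested. The platform annotation supplied with the values paired 20826 of them with a single gene symbol, 436 with several symbols and 9780 with none, and the symbols stood for 14217 genes. No filter on dim probe sets was applied. The number of arrays limits the precision of every value, since arrays carry no count of molecules.

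Models were fitted per tissue in limma 3.58.1 (R 4.3.3) with a mean for each of the 8 groups of 24 arrays and moderated variances. Each later group was set against its own 0 h group, which gave 6 contrasts per tissue and 12 in all. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with 0.05 as the threshold. Whether the doses differed in their time courses was tested with a moderated F test over 3 contrasts per tissue, each the change at 18 mg/kg minus the change at 3 mg/kg. The 0 h groups of both dose arms were set against each other in the same fit. Whether the tissues differed was tested per dose with an F test of the same form over all 48 arrays. All tests were two-sided. Log2 changes are printed with the model's standard error (SE), and group means with their SD.

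Gene lists were written before the data were examined, 30 for cortex and 37 for liver and 53 in all. They covered transmitter receptors, activity-induced genes, cell type markers, the circadian clock, stress responses, drug metabolism and liver metabolism. Each was tested with camera at a preset correlation of 0.01 between genes, with 1 probe set per gene, and adjusted over all lists and the 6 contrasts of the tissue. Camera with an estimated correlation and fry were run beside it. For each list the members past the threshold were counted over all probe sets and when adjusted over the list alone.

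Genes named in the text followed a rule written before the data were examined, and LOC and RGD names were passed over. A gene was represented by its single-symbol probe set with the highest mean over the tissue's 24 arrays. The rule took the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap the 0 h arrays. It added up to 4 passing members of each list whose test passed, the member with the smallest p of every other list, and 20 genes per tissue fixed in advance, of which 16 were measured in each. For the dose, 0 h and tissue tests it took up to 10 passing genes with the smallest p. The text prints only some of the genes that the rule took. In the tissue test after 3 mg/kg, for example, Slc22a25 (F test adjusted p = 0.027) is left out. Any gene named outside this rule is said to have been chosen after its values were seen. The fixed genes were also compared between the 6 arrays of 0 h and the 18 later arrays of a tissue by exact permutation of the difference in means over all 134596 splits, adjusted over 32 tests; this comparison was chosen after the values were seen.

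RNA integrity was measured per array as the log2 difference between the 3' and 5' control probe sets of actin and of GAPDH, which grows as RNA degrades. RNA from liver was followed in cortex arrays by the mean of 7 hepatocyte transcripts, and the spread of each array by the SD of its log2 values. The models were tested on simulated data made from the arrays' own spread. Each probe set was drawn independently with normal noise. The simulated arrays thus held no correlation between probe sets and no outlying arrays, and recovery in the real arrays can differ. In cortex at 4 h after 18 mg/kg, 87% of probe sets changed by 1 log2 unit and 98% of those changed by 2 were recovered. In liver at 4 h after 18 mg/kg the figures were 34% and 80%, in the F test for a dose difference in liver 5% and 54%, and in the F test for a tissue difference at 18 mg/kg 29% and 85%.

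The alternatives fixed in advance were quantile normalisation within a tissue, centring of array medians, a filter that kept the brighter probe sets, a variance trend with robust moderation, the replicate number as a block, 1 probe set per gene, a fit on the 6 arrays compared, both 0 h groups pooled as control, the doses compared without their 0 h groups, and leaving out each array in turn. For the F tests of dose and tissue differences all arrays with the same number were left out together. Those added after the data were seen were the mean 3' minus 5' gap as a covariate, alone and with the hepatocyte mean, only arrays with an actin gap of at most 3, only arrays with a hepatocyte mean of at most 8, and liver without the 2 arrays whose SD lay under 1.6, alone and with the gap covariate. No array was left out of the reported values. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for permutation tests and plots.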

Results

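RDX was given to rats at doses chosen not to cause seizures, and transcripts were measured in cortex and liver at 0, 4, 24 and 48 h. Each of the 16 groups had 3 arrays. Tissue identity was clear: Snap25, a synaptic vesicle release protein, averaged 13.25 ± 0.11 (SD, n = 24) on the log2 scale in cortex and 5.33 ± 0.54 in liver, and Alb, the serum albumin gene, averaged 14.31 ± 0.079 in liver. Alb ranged from 6.96 to 14.02 across the 24 cortex arrays.

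RNA measures differed between cortex groups. The actin 3' minus 5' gap averaged 2.89 ± 0.897 (SD, n = 3) at 0 h in the 3 mg/kg arm and 2.09 ± 0.378, 2.09 ± 0.0808 and 2.34 ± 0.337 at 4, 24 and 48 h. In the 18 mg/kg arm it averaged 2.65 ± 0.882 at 0 h and 3.66 ± 0.351, 3.3 ± 1.09 and 3.98 ± 0.902 later. The gap thus changed in opposite directions in the 2 arms. It exceeded 3 in 10 of the 24 cortex arrays, which lay between -62.7 and -22.1 on the first principal component (41.5% of the variance), while the other 14 lay between 4.83 and 30.5. The mean of 7 hepatocyte transcripts exceeded 8 in 7 cortex arrays and was at most 6.46 in the other 17. In liver, 2 arrays had compressed values: 3 mg/kg 0 h replicate 2 (SD of log2 values 1.492) and 18 mg/kg 4 h replicate 1 (SD 1.383).

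**Figure D1:**
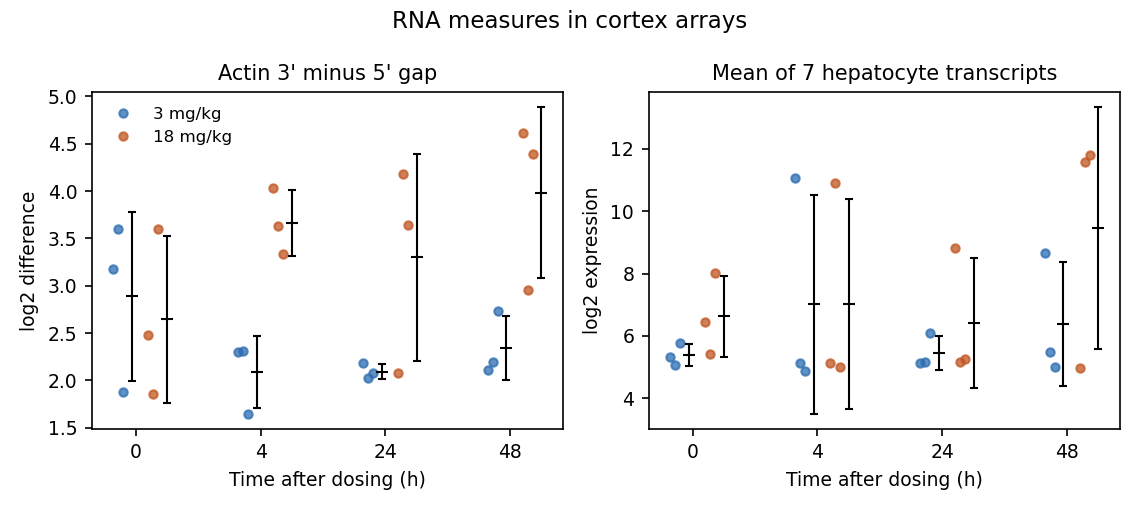
The 3' minus 5' gap of actin (left, log2 difference) and the mean of 7 hepatocyte transcripts (right, log2 expression) in each cortex array, by time after dosing (h) and dose; points are arrays and bars are means ± SD (n = 3). The gap at 48 h after 18 mg/kg averaged 3.98 and at 24 h after 3 mg/kg 2.09, and the hepatocyte mean reached 11.8 at 48 h after 18 mg/kg.

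The comparison of 4 h with 0 h after 3 mg/kg asked what the low dose did early in cortex. No gene passed. Dbp, a clock output transcription factor, was 2.23-fold higher in all 3 arrays (log2 1.16 ± 0.18 SE, n = 3 per group), with adjusted p = 0.14. Arc and Fos, genes induced by neuronal activity, had log2 changes of -1.44 ± 0.43 (adjusted p = 0.34) and -0.97 ± 0.56 (adjusted p = 0.44). Slc17a7, the vesicular glutamate transporter of cortical pyramidal neurons, had a log2 change of 1.46 ± 0.52 (adjusted p = 0.36). The change was 0.78 with the 3' minus 5' gap as a covariate and 0.22 with only the arrays at a gap of at most 3. That limit kept only replicate 3 of the 0 h group, so the 0.22 could not test whether the change depended on the gap. The single arrays did go with such a dependence. Slc17a7 was lower in each of the 10 cortex arrays with an actin gap over 3 than in any of the other 14. Within the 0 h group, replicates 1 and 2 (gaps of 3.18 and 3.6) lay below replicate 3 (gap of 1.88). The level thus followed the gap there without a difference in dose or time. Of 30 gene lists, 6 passed camera. The immediate early list had 23 of 31 measured members below 0, a median log2 change of -0.13 and camera adjusted p = 0.013, against adjusted p = 0.73 with an estimated correlation. When adjusted over the list alone 1 member was higher and 2 lower. Ribosomal protein genes had a median of 0.26 (16 of 20 above 0, camera adjusted p = 0.00049, and adjusted p = 0.68 with an estimated correlation), and 0 passed when adjusted over the list alone. The clock list, with 17 members measured, did not pass (camera adjusted p = 0.059), but 5 members were higher and 1 lower when adjusted over the list alone, among them Nr1d1, a clock repressor, at log2 0.62 ± 0.13. limma called 0 of 31042 probe sets, with 3905 at an unadjusted p under 0.05. The groups did not overlap in 16.1% of probe sets, where chance gives 10%. Without 3 mg/kg 0 h replicate 3, 33 probe sets passed, Dbp among them, and the immediate early list missed the threshold (adjusted p = 0.11). It also did without 3 mg/kg 4 h replicate 2 (adjusted p = 0.098), and without 3 mg/kg 0 h replicate 2 the ribosomal list missed it (adjusted p = 0.064).

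At 24 h after 3 mg/kg 14 genes changed in cortex. Inpp4b, a phosphoinositide phosphatase, rose 2.43-fold (log2 1.28 ± 0.20 SE, n = 3 per group; adjusted p = 0.019), and Rgs18, a regulator of G protein signalling, rose 2.06-fold (log2 1.05 ± 0.14; adjusted p = 0.0091). Calb2, the calcium-binding protein calretinin of a class of interneurons, rose 1.98-fold (log2 0.99 ± 0.16; adjusted p = 0.029). Nnat, the membrane proteolipid neuronatin, rose 2.05-fold and Pbx3, a homeodomain transcription factor, 1.96-fold. Arhgap6, Bex4, Rd3l and Necab2 also rose, by log2 1.13, 0.94, 0.93 and 0.72. Nrcam, a neuronal cell adhesion molecule, fell 1.55-fold (log2 -0.63 ± 0.12; adjusted p = 0.043). In the list of interneuron neuropeptides and markers, 12 of 14 members lay above 0; Calb2 passed over all probe sets. When adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 6e-04, and adjusted p = 0.51 with an estimated correlation). Striatal markers had a median log2 change of 0.94, and none of the 12 passed over all probe sets, while 10 were higher when adjusted over the list alone (camera adjusted p = 3.6e-05, and adjusted p = 0.68 with an estimated correlation). The neuropeptide precursors Tac1 (1.55 ± 0.35) and Penk (0.94 ± 0.22) were among them and were chosen after their values were seen. The mean of these markers was 7.81 in 3 mg/kg 0 h replicate 3, against 9.12 and 9.19 in the other arrays of that group, and without this array camera gave adjusted p = 0.063 for the list. The list also passed at 4 and 48 h after 3 mg/kg against the same 0 h arrays, with medians of 0.69 and 0.53 (camera adjusted p = 0.00013 and 0.029, adjusted p = 0.68 and 0.76 with an estimated correlation, and 0.34 and 0.95 without that array). At 48 h it missed the threshold without 48 h replicate 1 (0.21) or 3 (0.078) as well. Ribosomal protein genes had a median of 0.37 and 12 of 20 were higher when adjusted over the list alone (camera adjusted p = 2e-05, and adjusted p = 0.68 with an estimated correlation), beside a fall of the 3' minus 5' gap of actin by 0.8, and it also passed with the gap as a covariate (adjusted p = 7.9e-06). In all, 23 probe sets passed, 18 higher and 5 lower, for 14 genes. In 19.6% of probe sets the arrays did not overlap, where chance gives 10%. The count was 0, 5 and 125 without 3 mg/kg 0 h replicates 1, 2 and 3, and 3, 4 and 0 without 24 h replicates 1, 2 and 3. It was 0 with both 0 h groups pooled. With the replicate block, Arhgap6, Nnat, Pbx3, Necab2 and Nrcam missed the threshold (adjusted p from 0.053 to 0.067), and with the gap as a covariate Nnat (0.07) and Nrcam (0.075) did. Without the arrays over a gap of 3 the 0 h group kept only replicate 3, so that fit could not test whether the 23 calls depended on the gap.

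No gene passed in cortex at 48 h after 3 mg/kg. Egr1, an activity-induced transcription factor, had a log2 change of -0.69 ± 0.17 SE (n = 3 per group; adjusted p = 0.28), lower in all 3 arrays than in the 0 h arrays, and Arc had -1.21 ± 0.43 (adjusted p = 0.31). The immediate early list had 27 of 31 members below 0 and a median of -0.21 (camera adjusted p = 6.7e-05, and adjusted p = 0.68 with an estimated correlation), with 2 lower when adjusted over the list alone. Ribosomal protein genes had a median of 0.29, with 6 higher when adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.68 with an estimated correlation). Genes of oxidative phosphorylation had medians of 0.12, 0.22 and 0.19 at 4, 24 and 48 h after 3 mg/kg (camera adjusted p = 0.02, 0.00018 and 0.00082, and adjusted p = 0.74, 0.68 and 0.68 with an estimated correlation). With the gap as a covariate they had adjusted p = 0.59, 0.0026 and 0.0077. limma called 0 probe sets, with 4026 at an unadjusted p under 0.05 and 20.6% without overlap, where chance gives 10%. Without 3 mg/kg 0 h replicate 3 the count was 4. At 4 h the oxidative phosphorylation list missed the threshold without 3 mg/kg 0 h replicate 2 (adjusted p = 0.33) or 4 h replicate 3 (adjusted p = 0.13).

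The same question was asked of the high dose. At 4 h after 18 mg/kg no gene passed in cortex. Sgk1, a kinase gene induced by glucocorticoids, was 1.46-fold higher (log2 0.54 ± 0.16 SE, n = 3 per group; adjusted p = 0.45), Nr1d1 had a log2 change of 0.46 ± 0.13, and Arc and Fos had -1.22 ± 0.43 and -1.19 ± 0.56, all with adjusted p = 0.45. Slc17a7 was at -1.14 ± 0.52 (adjusted p = 0.45), and at -0.29 with the 3' minus 5' gap as a covariate. Every 4 h array of this arm had an actin gap over 3, where Slc17a7 was low in all cortex arrays. The immediate early list had a median of -0.21 with 2 members lower when adjusted over the list alone (camera adjusted p = 0.00049, and adjusted p = 0.68 with an estimated correlation). Genes of oxidative phosphorylation had a median of -0.16, with 24 of 29 below 0 (camera adjusted p = 0.00021, and adjusted p = 0.68 with an estimated correlation), beside a rise of the actin gap by 1.02, and adjusted p = 0.055 with the gap as a covariate. limma called 0 probe sets, with 3420 at an unadjusted p under 0.05 and 17% without overlap, where chance gives 10%. With only the arrays low in hepatocyte transcripts the count was 1289. That fit left out the 0 h array with an actin gap of 3.6. It kept gaps of 2.48 and 1.86 at 0 h and of 4.03 and 3.33 at 4 h. RNA integrity and dose therefore cannot be told apart in that count.

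At 24 h after 18 mg/kg no gene passed in cortex. Arc had a log2 change of -1.23 ± 0.43 SE (n = 3 per group; adjusted p = 0.82) and Fos of -0.98 ± 0.56 (adjusted p = 0.84). The immediate early list had a median of -0.12, with 23 of 31 below 0 and 2 lower when adjusted over the list alone (camera adjusted p = 6.7e-05, and adjusted p = 0.68 with an estimated correlation). Pyramidal neuron markers had a median of -0.16, with 10 of 14 below 0 and 0 passing when adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation). Striatal markers had a median of 0.35, with 12 of 12 above 0 and 0 passing when adjusted over the list alone (camera adjusted p = 0.035, adjusted p = 0.76 with an estimated correlation, and 0.18 with the gap as a covariate). Genes of oxidative phosphorylation had a median of -0.08 (camera adjusted p = 0.025, adjusted p = 0.74 with an estimated correlation, and 0.59 with the gap as a covariate). limma called 0 probe sets, with 1858 at an unadjusted p under 0.05 and 8.91% without overlap, where chance gives 10%. Without 18 mg/kg 24 h replicate 1 the count was 2 and the immediate early list missed the threshold (adjusted p = 0.18). With only the arrays low in hepatocyte transcripts the count was 1034. That fit kept actin gaps of 2.48 and 1.86 at 0 h and of 4.18 and 3.64 at 24 h. RNA integrity and dose therefore cannot be told apart in that count. The striatal list missed the threshold without 18 mg/kg 0 h replicates 2 and 3 (adjusted p = 0.2 and 0.067) or 24 h replicates 1 and 3 (0.13 and 0.097). The pyramidal list missed it without 18 mg/kg 0 h replicate 1 (adjusted p = 0.093) or 24 h replicate 3 (0.071), and the oxidative phosphorylation list without 0 h replicates 1 and 2 (0.14 and 0.23) or 24 h replicates 2 and 3 (0.34 and 0.37).

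At 48 h after 18 mg/kg no gene passed in cortex, and Fos and Arc had their largest changes of the 6 comparisons. Fos was 3.97-fold lower (log2 -1.99 ± 0.56 SE, n = 3 per group; adjusted p = 0.11), Arc 3.17-fold lower (log2 -1.66 ± 0.43; adjusted p = 0.1) and Egr1 1.58-fold lower (log2 -0.66 ± 0.17; adjusted p = 0.1), each below every 0 h array. Of 31 members of the list, 28 lay below 0, and 10 were lower and 2 higher when adjusted over the list alone. Nr4a1, an orphan nuclear receptor, was at -1.69 ± 0.27 and Junb, a subunit of the AP-1 factor, at -1.24 ± 0.26 (adjusted p = 0.054 and 0.079), both chosen after their values were seen. Nr4a1 passed after quantile normalisation (adjusted p = 0.031), centring of medians (0.041), with only brighter probe sets (0.028) and with 1 probe set per gene (0.022), where the counts were 32, 23, 29 and 33, and not with the gap as a covariate, where the count was 0. The median was -0.35 (camera adjusted p = 1.1e-05, and adjusted p = 0.68 with an estimated correlation). Sgk1 was at 0.53 ± 0.16 (adjusted p = 0.12). Genes of oxidative phosphorylation had a median of -0.14 (camera adjusted p = 0.0076, and adjusted p = 0.73 with an estimated correlation), beside a rise of the actin gap by 1.33 and of the hepatocyte mean by 2.83. With the 3' minus 5' gap as a covariate this list turned upward (adjusted p = 0.46), also with liver transcripts as a further covariate (adjusted p = 0.75). limma called 0 probe sets, with a smallest adjusted p of 0.053, 5151 at an unadjusted p under 0.05 and 14.8% without overlap, where chance gives 10%. The count was 611 without 18 mg/kg 0 h replicate 3, and 352, 2146 and 1 without 48 h replicates 1, 2 and 3. Junb and Nr4a1 passed without 0 h replicate 3 (adjusted p = 0.034 for both) and without 48 h replicate 2 (0.013 and 0.0032), and Nr4a1 without 48 h replicate 1 (0.013). Without 48 h replicate 2 Egr1 passed, while without 48 h replicate 1 the oxidative phosphorylation list missed the threshold (adjusted p = 0.12).

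Over both arms together, Arc, Egr1 and Fos were lower at later times than at 0 h. Arc averaged 9.15 ± 0.28 (SD, n = 6) at 0 h and 7.84 ± 0.59 (n = 18) later, and 16 of the 18 later arrays lay below every 0 h array (exact permutation p = 3e-05, adjusted 0.00095). Egr1 averaged 11.98 ± 0.091 and 11.46 ± 0.28 (exact p = 0.00016, adjusted 0.0026), and Fos 8.99 ± 0.42 and 7.83 ± 0.76 (exact p = 0.0021, adjusted 0.014). Dbp averaged 8.52 at 0 h and 9.09 later (exact p = 0.0015, adjusted 0.014) and Nr1d1 7.70 and 8.03 (exact p = 0.0022, adjusted 0.014). The other 11 fixed cortex genes that were measured did not pass, including Bdnf, a neurotrophin, at 7.69 and 7.63 (adjusted 0.87) and Gad1, an enzyme that makes GABA, at 12.47 and 12.53 (adjusted 0.58). In liver, Nr1d1 averaged 5.64 ± 0.45 at 0 h and 7.34 ± 1.4 later (exact p = 0.0069, adjusted 0.037), and the other 15 fixed genes did not pass.

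**Figure D2:**
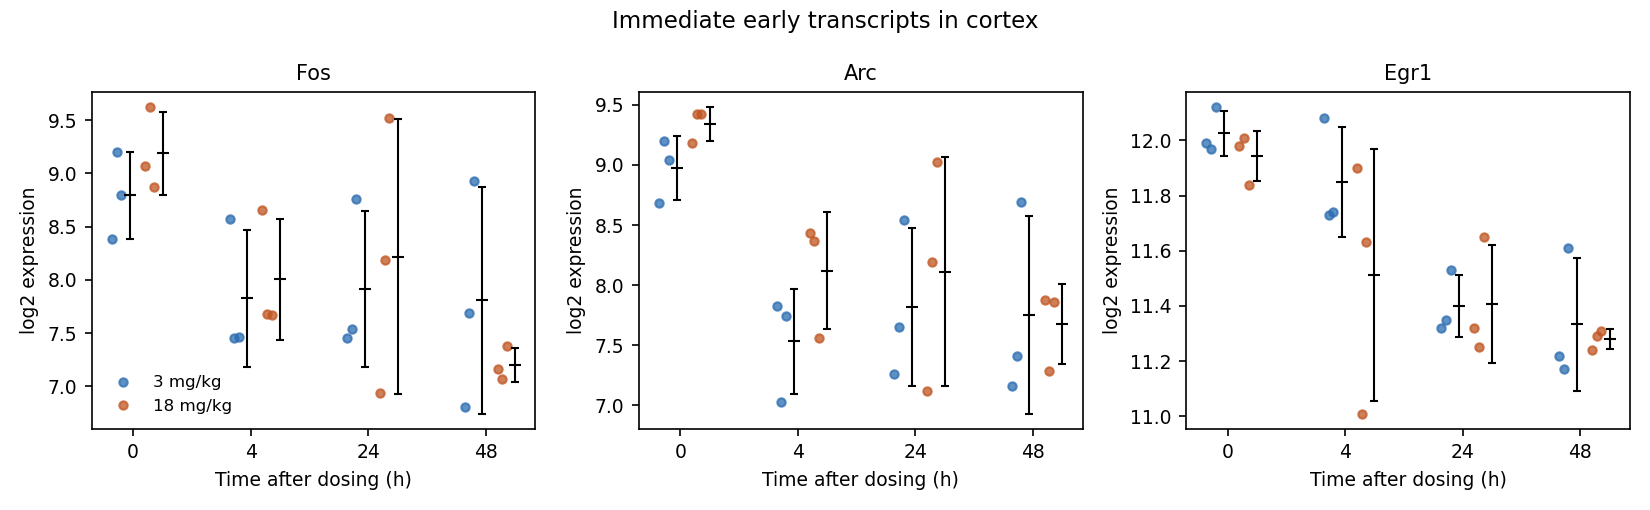
Expression (log2) of Fos, Arc and Egr1 in each cortex array by time after dosing (h) and dose; points are arrays and bars are means ± SD (n = 3). Arc averaged 9.15 in the 6 arrays of 0 h and 7.84 in the 18 later arrays.

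RDX is known to block the GABA type A receptor, so its subunits were among the lists. None of its 13 measured subunit genes passed in any of the 6 cortex contrasts, over all probe sets or adjusted over the list alone, and the list's median log2 change lay between -0.11 and 0.018 (camera adjusted p from 0.14 to 0.95). Glutamate receptor genes (21 measured) had medians between -0.093 and 0.014 (camera adjusted p from 0.76 to 0.95), and 2 member calls were made over the 6 contrasts when adjusted over the list alone. Astrocyte markers (13 measured) had medians between -0.13 and 0.14 and microglia markers (16 measured) between -0.08 and 0.14, and neither list passed (camera adjusted p at least 0.26 and 0.12). Over the 6 contrasts 0 astrocyte and 11 microglia member calls were made when adjusted over the list alone.

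The dose arms were compared with each other in cortex. Scn2a, a voltage-gated sodium channel subunit, was the only gene whose time course differed between the doses (adjusted p = 0.034): the change after 18 mg/kg exceeded that after 3 mg/kg by log2 0.06 at 4 h, 0.2 at 24 h and 0.96 at 48 h. In all 1 probe set of 31042 passed, with 5175 at an unadjusted p under 0.05. At 48 h alone the change from 0 h differed in 529 probe sets, with 214 changes higher and 315 lower after the high dose. At 4 and 24 h limma called 0, with 6784 and 4193 at an unadjusted p under 0.05. The mean 3' minus 5' gap changed by -0.682 at 48 h after 3 mg/kg and by 1.78 after 18 mg/kg, and the hepatocyte mean by 0.987 and 2.83. The 529 was not recomputed under the alternatives, so RNA measures and dose cannot be told apart in it. Across probe sets, the changes at the 2 doses correlated at r = -0.559, -0.289 and -0.409 at 4, 24 and 48 h; probe sets are not independent replicates. At 0 h the arms did not differ by limma, with 0 calls and 1349 at an unadjusted p under 0.05. Scn2a missed the threshold without all arrays numbered replicate 1 (adjusted p = 0.52) and without replicate 2 (adjusted p = 0.34). The F test called 2531 probe sets without replicate 3, and with the 3' minus 5' gap as a covariate it called 0 (Scn2a adjusted p = 0.17). Scn2a also missed the threshold after quantile normalisation (0.077), centring of medians (0.1) and with the replicate block (0.11).

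In liver, the low dose was followed at 4 h by a change in clock genes. Nr1d1, a repressor in the circadian clock, rose 9.27-fold (log2 3.21 ± 0.50 SE, n = 3 per group; adjusted p = 0.011), its relative Nr1d2 7.51-fold (log2 2.91 ± 0.45; adjusted p = 0.011) and Per3, a period gene, 3.71-fold (log2 1.89 ± 0.25; adjusted p = 0.0061). Cry1, a clock repressor of another phase, fell 3.41-fold (log2 -1.77 ± 0.28; adjusted p = 0.014). Retreg1, an endoplasmic reticulum turnover receptor, rose 7.61-fold (log2 2.93 ± 0.43; adjusted p = 0.0074), Cxcl1, a neutrophil chemokine, rose 4.13-fold (log2 2.05 ± 0.33; adjusted p = 0.014), and Ppard, a lipid-sensing nuclear receptor, fell 3.1-fold (log2 -1.63 ± 0.23; adjusted p = 0.0074). These were the 7 probe sets that passed, of 4402 at an unadjusted p under 0.05. In the clock list, 3 of 17 measured members rose and 1 fell, and 5 were higher and 2 lower when adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.21), and Dbp was at 1.68 ± 0.38 (adjusted p = 0.18). Cell cycle genes had a median of -0.55, with 19 of 21 below 0 and 4 lower when adjusted over the list alone (camera adjusted p = 4.8e-08, and adjusted p = 0.83 with an estimated correlation). Interferon response genes had a median of 0.72 and acute phase genes of 0.67, with 4 and 2 members higher when adjusted over the lists alone (camera adjusted p = 0.00042 and 0.0018, and adjusted p = 0.83 with an estimated correlation for both). The control group holds a compressed array, and without the 2 compressed arrays 8 probe sets passed, 5 of them shared with the 7, and Cry1 (adjusted p = 0.056) and Cxcl1 (0.08) missed the threshold. The count was 0, 3 and 1809 without 3 mg/kg 0 h replicates 1, 2 and 3, and 1, 0 and 3 without 4 h replicates 1, 2 and 3. Without 0 h replicate 2 the acute phase list missed the threshold (adjusted p = 0.093).

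At 24 h after 3 mg/kg no gene passed in liver. Cyp1a2, a drug-metabolising enzyme, was 3.11-fold higher (log2 1.64 ± 0.48 SE, n = 3 per group; adjusted p = 0.1), above every 0 h array, and Nr1d1 was at 1.28 ± 0.50 (adjusted p = 0.17). The lowest 0 h value of Cyp1a2 was that of the compressed replicate 2, and without this array its log2 change was 0.86. The highest change with an array left out was 2.15, and the lowest under the other alternatives was 0.42. Ribosomal protein genes had a median log2 change of 1.1 and genes of oxidative phosphorylation of 0.86, with 19 of 20 and 25 of 29 above 0 (camera adjusted p = 0.0088 and 0.0028, and adjusted p = 0.83 with an estimated correlation for both). None of their members passed when adjusted over the list alone. The actin 3' minus 5' gap fell by 0.828, and with the gap as a covariate and without the compressed arrays both lists missed the threshold (adjusted p = 0.088 and 0.31), and 2 of 37 lists passed instead of 8. limma called 0 probe sets, with a smallest adjusted p of 0.078 and 6213 at an unadjusted p under 0.05. Arrays with the same number were alike in this comparison (correlations of 0.181 to 0.421), and with the replicate number as a block the count was also 0. The count was 3777 without 3 mg/kg 0 h replicate 3, when Cyp1a2 passed, and 2 without 24 h replicate 3. Without the compressed 0 h replicate 2 both lists missed the threshold (adjusted p = 0.15 and 0.12).

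At 48 h after 3 mg/kg 1482 genes passed in liver, and this count depended on single arrays and on an RNA measure. Ncoa4, the receptor that delivers ferritin for degradation, rose 7.38-fold (log2 2.88 ± 0.59 SE, n = 3 per group; adjusted p = 0.023), Suclg2, a citric acid cycle enzyme subunit, 7.07-fold (log2 2.82 ± 0.65; adjusted p = 0.025) and Gstm2, a glutathione transferase, 6.42-fold (log2 2.68 ± 0.73; adjusted p = 0.032). Gabarapl1, an autophagy protein, rose by log2 2.74, Ces1d, a carboxylesterase, by 2.69 and Igfbp7, an insulin-like growth factor binding protein, by 2.76. Mt1, the metal-binding metallothionein, fell 3.48-fold (log2 -1.80 ± 0.44; adjusted p = 0.026) and Khsrp, an RNA-binding protein that promotes mRNA decay, 3.76-fold (log2 -1.91 ± 0.45; adjusted p = 0.025). Cyp1a2 rose 3.92-fold and Bmal1, the clock activator, 4.39-fold. In all, 2898 probe sets passed, 1864 higher and 1034 lower, of 9936 at an unadjusted p under 0.05. In 36.3% of probe sets the arrays did not overlap, where chance gives 10%. The median of all probe sets changed by -0.16, and after centring of array medians 2882 passed, 2320 higher and 562 lower.

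Members of several metabolic groups rose at that time, when 1482 of all 14217 genes passed in either direction. The counts of 4 of 29, 3 of 24 and 2 of 16 given here lie near that share, and the others lie above it. Of 15 NRF2 target genes, which respond to oxidative stress, 3 rose, Txnrd1 (log2 1.30 ± 0.33), Srxn1 (0.99 ± 0.28) and Gclm (0.81 ± 0.23), and 7 were higher when adjusted over the list alone. Of 9 targets of the xenobiotic receptor PXR, 3 rose, Cyp3a18 (2.16 ± 0.56), Cyp3a9 (1.87 ± 0.41) and Abcb1a (1.38 ± 0.29), and 5 were higher when adjusted over the list alone. Of 19 glutathione transferases 4 rose, and of 29 genes of oxidative phosphorylation 4 rose, including Sdha (1.88 ± 0.47) and Cox5b (1.69 ± 0.52). Of these groups 8 and 11 were higher when adjusted over the lists alone. Of 24 amino acid and urea cycle genes 3 rose, including Oat (2.35 ± 0.63) and Gls2 (1.87 ± 0.53), and of 17 genes of heme synthesis and iron 3 rose, including Hamp, the iron hormone hepcidin (1.93 ± 0.36), and Cpox (1.79 ± 0.53). Here 7 and 9 were higher when adjusted over the lists alone. Markers of other liver cells rose as well: 3 of 16 endothelial genes, among them Kdr (0.87 ± 0.24), and 2 of 16 stellate cell genes, among them Timp1 (1.91 ± 0.44), with 4 and 5 higher when adjusted over the lists alone. Of 15 Kupffer cell and monocyte genes 5 rose, among them Ptprc, the leukocyte antigen CD45 (1.25 ± 0.28), and 5 were higher and 1 lower when adjusted over the list alone, although this list did not pass camera (adjusted p = 0.079). The other 8 lists passed camera with adjusted p from 0.0063 to 0.043, and each had adjusted p = 0.83 with an estimated correlation.

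The 0 h group of this comparison includes the compressed replicate 2, and its means were spread widely, as for Ncoa4 (6.86 ± 1.4 SD). The actin 3' minus 5' gap fell by 0.699 between the groups. With the gap as a covariate and without the 2 compressed arrays 0 probe sets passed, the smallest adjusted p of the named genes was 0.87, and 6 of the 8 lists missed the threshold (adjusted p from 0.05 to 0.76). The 2898 became 0 without 0 h replicate 2, and 1372 (878 higher, 494 lower) without both compressed arrays, which also takes an array from another group. The count was 1453 and 7764 without 0 h replicates 1 and 3, 0, 148 and 0 without 48 h replicates 1, 2 and 3, 0 with both 0 h groups pooled and 0 in a fit on the 6 arrays alone. Quantile normalisation gave 1671 (960 higher, 711 lower). Without 0 h replicate 2, 4 of the 8 lists missed the threshold, the NRF2, oxidative phosphorylation, amino acid and stellate lists (adjusted p = 0.083, 0.1, 0.11 and 0.17). The NRF2 list also missed it without 0 h replicate 1 (0.058) and 48 h replicate 3 (0.055), the endothelial list without 0 h replicates 1 and 3 and 48 h replicate 1 (0.051, 0.072 and 0.06), and the stellate list without 0 h replicate 3 and 48 h replicates 1 and 3 (0.086, 0.063 and 0.063).

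At 4 h after 18 mg/kg 3 clock genes changed in liver. Nr1d1 rose 8.86-fold (log2 3.15 ± 0.50 SE, n = 3 per group; adjusted p = 0.016), Per3 3.59-fold (log2 1.84 ± 0.25; adjusted p = 0.0071), and Cry1 fell 4.03-fold (log2 -2.01 ± 0.28; adjusted p = 0.0071). Nr1d2, which rose after 3 mg/kg, did not pass (log2 1.98 ± 0.45; adjusted p = 0.24, and 0.019 without the compressed arrays). Nr1d1, Per3 and Cry1 were shared with 3 mg/kg at 4 h, 2 up and 1 down, where chance gives 0.000805 and 0.000193. Ablim3, an actin-binding protein, rose 4.14-fold (log2 2.05 ± 0.33; adjusted p = 0.016), and Inhba, a subunit of activin, fell 2.52-fold (log2 -1.33 ± 0.24; adjusted p = 0.044). Dbp was at 1.88 ± 0.38 (adjusted p = 0.11). In the clock list 2 of 17 members rose and 1 fell, and 4 were higher and 5 lower when adjusted over the list alone, with medians and means of opposite sign (-0.32 and 0.077; camera adjusted p = 0.98). Cholesterol synthesis genes had a median of -0.94 and fatty acid synthesis genes of -0.83, with 20 of 20 and 20 of 22 below 0 and 4 and 6 lower when adjusted over the lists alone (camera adjusted p = 1e-05 and 1.1e-05, and adjusted p = 0.83 with an estimated correlation for both). Fasn, fatty acid synthase, was at -0.82 ± 0.24 (adjusted p = 0.4). Cell cycle genes had a median of -0.53, with 19 of 21 below 0 and 2 lower when adjusted over the list alone (camera adjusted p = 8.9e-05, and adjusted p = 0.83 with an estimated correlation). In all, 8 probe sets passed, 5 higher and 3 lower, of 3536 at an unadjusted p under 0.05. Inhba missed the threshold after quantile normalisation (adjusted p = 0.41), with a variance trend (0.2) and with the replicate block (0.092), and Nr1d1 and Ablim3 after centring of medians (0.073 for both). The group holds a compressed array, and 14 passed without the 2 compressed arrays, with all 8 among them. The actin 3' minus 5' gap changed by -1.09 between the groups. Without the 2 compressed arrays 7 of 37 lists passed instead of 15, the cholesterol, fatty acid and cell cycle lists still among them. The count was 0, 0 and 3 without 18 mg/kg 0 h replicates 1, 2 and 3, and 33 and 3 without 4 h replicates 2 and 3. Without the compressed 4 h replicate 1 Dbp passed.

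**Figure D3:**
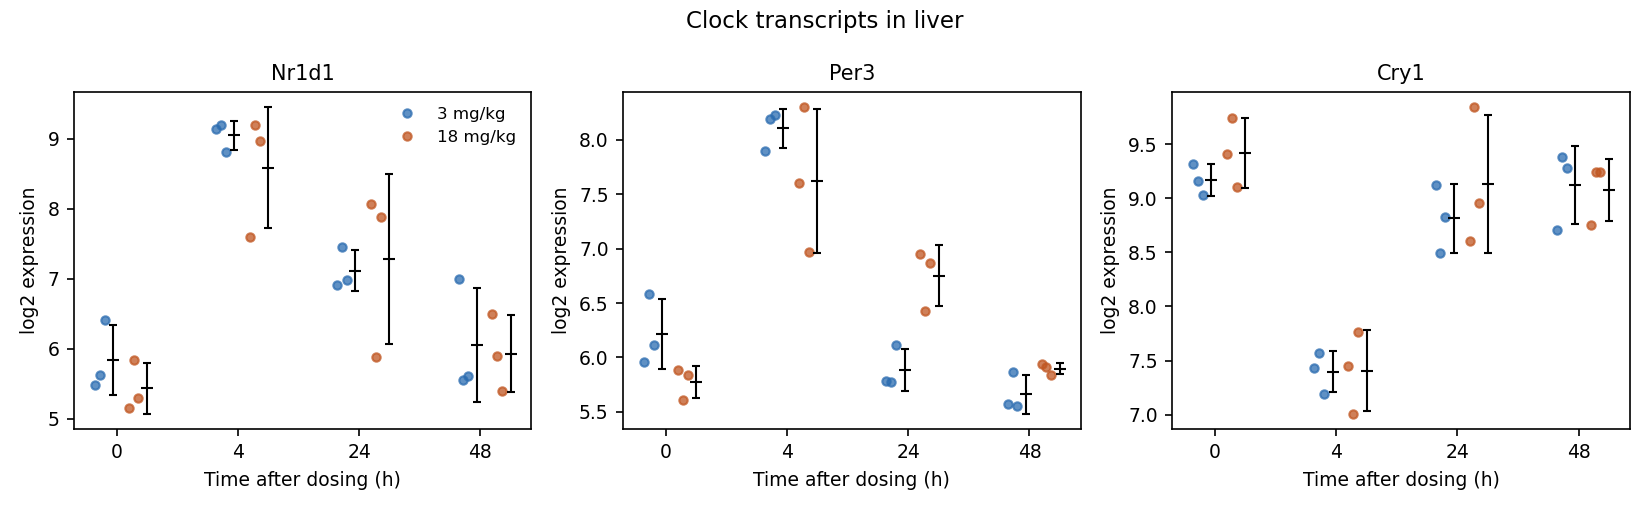
Expression (log2) of Nr1d1, Per3 and Cry1 in each liver array by time after dosing (h) and dose; points are arrays and bars are means ± SD (n = 3). At 4 h Nr1d1 averaged 9.05 after 3 mg/kg and 8.58 after 18 mg/kg, against 5.84 and 5.44 at 0 h.

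At 24 h after 18 mg/kg no gene passed in liver, but cell cycle genes were lower as a group. Of 21 measured, 18 lay below 0 and the median log2 change was -0.93; 0 passed over all probe sets and 13 were lower when adjusted over the list alone. Top2a, a DNA topoisomerase of dividing cells, was at -1.18 ± 0.28 (SE, n = 3 per group) and Birc5, the mitotic protein survivin, at -1.02 ± 0.21, both chosen after their values were seen. The list passed camera (adjusted p = 1.2e-24), also with an estimated correlation (adjusted p = 0.041 with an estimated correlation). Fatty acid synthesis genes had a median of -0.35 and PXR targets of 0.3 (camera adjusted p = 5.2e-05 and 0.0014, and adjusted p = 0.83 with an estimated correlation for both). Nr1d1 was at 1.84 ± 0.50 (adjusted p = 1). limma called 0 probe sets, with 753 at an unadjusted p under 0.05 and 9.74% without overlap, where chance gives 10%.

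At 48 h after 18 mg/kg, genes of cell division fell in liver. Ect2, which directs cytokinesis, fell 7.39-fold (log2 -2.88 ± 0.32 SE, n = 3 per group; adjusted p = 0.00015), the proliferation marker Mki67 6.03-fold (log2 -2.59 ± 0.34; adjusted p = 0.0011), Racgap1, a partner of Ect2, 5.28-fold (log2 -2.40 ± 0.30; adjusted p = 0.00061) and Cdk1, the mitotic kinase, 5.72-fold (log2 -2.52 ± 0.38; adjusted p = 0.0054). The cyclins Ccnb1 and Ccnb2 fell by log2 values of -2.14 and -2.19, the spindle and kinetochore genes Spc25, Knstrn and Nusap1 by -2.30, -2.17 and -2.08, and Cdkn3 by -2.59. All 30 probe sets that passed, for 26 genes, were lower, of 517 at an unadjusted p under 0.05. In the cell cycle list all 21 measured members lay below 0, 7 fell over all probe sets and 16 were lower when adjusted over the list alone. The median was -1.4 (camera adjusted p = 9.3e-71, and adjusted p = 0.00023 with an estimated correlation). The list's mean was 7.51 ± 0.14 (SD, n = 3) at 0 h and 6.99 ± 0.16, 6.75 ± 0.33 and 6.21 ± 0.24 at 4, 24 and 48 h, against 7.38 ± 0.47, 6.84 ± 0.062, 7.73 ± 0.11 and 7.31 ± 0.16 in the 3 mg/kg arm. Fatty acid synthesis genes had a median of 0.26, of the sign opposite to 24 h, and PXR targets of 0.28 (camera adjusted p = 0.00061 and 0.0042, and adjusted p = 0.83 with an estimated correlation for both). Fasn was at 0.67 ± 0.24 (adjusted p = 1). The 30 became 15, 5 and 15 without 18 mg/kg 0 h replicates 1, 2 and 3, and 5 and 13 without 48 h replicates 2 and 3. Of the 10 genes named here, 3 still passed without 0 h replicate 2 and 3 without 48 h replicate 2. With the replicate number as a block 17 passed, and 55 passed without the 2 compressed arrays. Ccnb1, Ccnb2 and Nusap1 missed the threshold with the replicate block (adjusted p = 0.09, 0.065 and 0.071), after quantile normalisation (0.082, 0.068 and 0.23) and after centring of medians (0.097, 0.062 and 0.065).

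**Figure D4:**
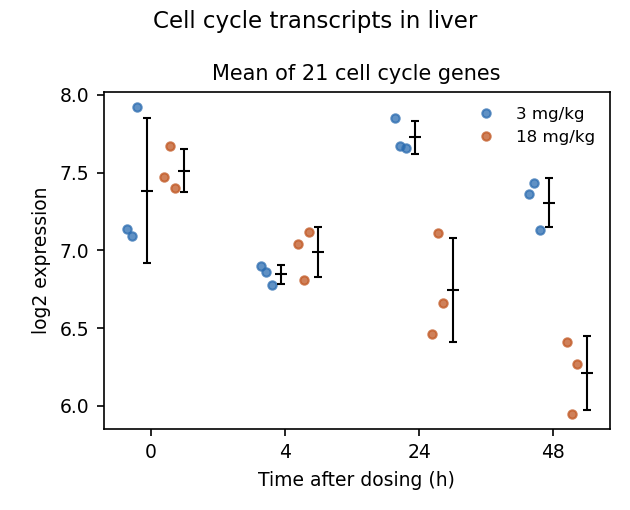
Mean expression (log2) of the 21 measured cell cycle genes in each liver array by time after dosing (h) and dose; points are arrays and bars are means ± SD (n = 3). At 48 h the mean was 6.21 after 18 mg/kg and 7.31 after 3 mg/kg.

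Whether the liver time courses differed between doses was tested directly. Cdk1 was the only named gene that passed the F test (adjusted p = 0.048): its change after 18 mg/kg differed from that after 3 mg/kg by log2 -0.46 at 4 h, -2.7 at 24 h and -3.22 at 48 h. In all 3 probe sets passed, of 2962 at an unadjusted p under 0.05, and the 3 single times gave 0 calls each by limma, with 5717, 2527 and 5786 at an unadjusted p under 0.05. As a group, the cell cycle genes differed between doses at 24 h and 48 h by camera (adjusted p = 3.6e-09 and 2.5e-07, and adjusted p = 0.75 with an estimated correlation for both). Cdk1 missed the threshold without all arrays of replicate 1, 2 or 3 (adjusted p = 0.76, 0.2 and 0.34), and the count was then 0 or 1. It also missed it after quantile normalisation (0.089), centring of medians (0.093), with the replicate block (0.057), with only brighter probe sets (0.056), with 1 probe set per gene (0.071) and without the compressed arrays (0.076, and 0.88 with the gap as a covariate). At 0 h the arms gave 0 calls by limma, with 6658 at an unadjusted p under 0.05, and 4123 without 3 mg/kg 0 h replicate 3.

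The last comparison asked whether liver and cortex changed differently. After 3 mg/kg the time courses of 91 probe sets differed between the tissues, of 4978 at an unadjusted p under 0.05. Per3 changed more in liver than in cortex by log2 1.58 at 4 h, and by -0.65 and -0.64 at 24 and 48 h (adjusted p = 0.00056). The difference for Cxcl1 was 2.19 at 4 h (adjusted p = 0.018), for Retreg1 2.86 at 4 h (adjusted p = 0.02), for Jam2, a junctional adhesion molecule, 1.94 at 48 h and for Lyst, a lysosomal trafficking regulator, 2.74 at 48 h (both adjusted p = 0.041). After 18 mg/kg, 40 probe sets differed, of 2062 at an unadjusted p under 0.05. Ect2, Racgap1, Mki67 and Cdkn3 changed by log2 -2.83, -2.62, -2.58 and -2.49 in liver relative to cortex at 48 h (adjusted p = 0.00023, 0.0012, 0.0026 and 0.0053), and Cry1 by -1.92 and Ppard by -1.35 at 4 h (adjusted p = 0.0053 and 0.0071). Fasn differed by -1.07 at 4 h and 0.65 at 48 h (adjusted p = 0.0071). The count after 3 mg/kg was 0, 2 and 345 without all arrays of replicates 1, 2 and 3, and 225 without the 2 compressed arrays; after 18 mg/kg it was 8, 3 and 3, and 79. After quantile normalisation Ppard (adjusted p = 0.57), Fasn (0.63) and Lyst (0.056) missed the threshold. Without replicate 1 the 5 genes named after 3 mg/kg all missed it (adjusted p = 0.5), and after 18 mg/kg Mki67, Cry1, Ppard and Fasn missed it whichever replicate was left out (from 0.052 to 0.55).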

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

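The tests of RNA integrity and of induction by the dose in cortex, and the 3 tests of other explanations for the fall of cell cycle genes, were chosen after the results were seen, as were the gap covariate and the fits without compressed arrays. The 2 tests for liver transcripts and the random splits were written before their own results were seen. The groups, gene lists, limma models, F tests and the leaving out of single arrays were fixed before the data were examined.

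The results in this paragraph stood out because a direct test found that doses or tissues differed, or because an RNA measure outside the comparisons exceeded every 0 h array. The F test for a dose difference gave 1 probe set in cortex, Scn2a with adjusted p = 0.034, and 3 in liver, among them Cdk1 with adjusted p = 0.048. At 48 h alone the dose difference in cortex gave 529, a count that was not recomputed under the alternatives and in which RNA measures and dose cannot be told apart. The tissues differed in 91 probe sets after 3 mg/kg and in 40 after 18 mg/kg. The actin 3' minus 5' gap averaged 3.98 in cortex at 48 h after 18 mg/kg and 3.66 at 4 h, above the highest 0 h cortex array at 3.6.

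Dose labels within each time, or tissue labels within each dose and time, were also exchanged at random in 100 draws that included the real assignment, after the mean of each arm and tissue was taken off. For the cortex dose difference 4 of 100 draws gave as many probe sets as the real 1, and another draw gave 1956, which points to a structure of the samples other than dose. For the liver dose difference 1 of 100 did, with 3 in the real assignment and at most 2 in any other. For the tissue difference after 3 mg/kg 1 of 100 did (91 against at most 1), and after 18 mg/kg 4 of 100 did (40, with 378 in another draw), which again points to a structure of the samples.

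Cortex changes at 3 and 18 mg/kg were of opposite sign across probe sets (r = -0.559, -0.289 and -0.409 at 4, 24 and 48 h; probe sets are not independent replicates). RNA integrity is a possible explanation: the slope of each probe set on the 3' minus 5' gap within groups correlated with the change, signed by the change in the gap, at 0.414 or more in all 6 contrasts, and with the gap as a covariate the doses correlated at 0.0141, 0.0583 and 0.15. Liver transcripts do not account for it, since without the 985 probe sets much brighter in liver the lowest correlation was -0.633. Whether the gap differed because of dose, dissection order or RNA handling stays open.

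Hepatocyte transcripts were high in 7 cortex arrays. RNA from liver may have entered them: over 305 probe sets the rise followed the level in liver, with Spearman rho of at least 0.661, and the estimated share of liver RNA was 1.5 to 3% in 4 of the arrays and 0.21 to 0.22% in the other 3. In those 3 arrays 83.3, 89.2 and 89.8% of the probe sets rose, below the 90% set before the test, which could not decide for all 7. For the 4 highest arrays the values argue against induction by the dose. In them 98 to 100% of the probe sets rose, with rho of 0.826 to 0.844. At 4 h after 3 mg/kg the group's arrays lay at 11.07, 5.118 and 4.872, and after 18 mg/kg at 5.142, 10.91 and 5.001. At 48 h after 18 mg/kg they lay at 4.983, 11.57 and 11.82. For the other 3 arrays induction cannot be told apart. The limit was set after the arrays were seen, and 0 groups had all 3 arrays over it. The only 0 h array over it lay at 8.02, and the 4 highest arrays were all from later times. How these transcripts came into the arrays stays open.

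Cell cycle genes fell in liver at 48 h after 18 mg/kg. With the gap as a covariate and without the 2 compressed arrays the median of the list was still -1.2. Neither compressed array is in the groups compared, so leaving them out could not by itself change this median and is no test of them. The lowest median of 5 lists of liver cell type markers was -0.16. High 0 h values in that arm do not account for it either, since the list lay lower than in the 3 mg/kg arm at 48 h itself, by a median of -0.9, with 21 of 21 genes lower. There was no vehicle group at 48 h and no count of dividing cells, no biological explanation was tested, and the count of genes depended on the arrays kept (5 to 21 probe sets when 1 was left out), so which cells carried the transcripts stays open.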

How the results depend on the processing

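Each count was recomputed under alternatives fixed before the data were examined and under 6 added afterwards. Of 338 recomputed counts, 218 stayed within 1.5 times and 120 moved. Of 1742 gene values, 1265 stayed on the same side of the threshold, 432 lost their call, 43 gained one and 2 reversed in sign. The 1265 include many values of genes that passed neither in the main fit nor in the alternative. They are therefore not a count of calls kept. Of 142 F tests of genes 94 kept their call and 48 were weaker. Of 528 list tests 417 stayed on the same side of the threshold, 107 lost their call and 4 reversed in direction. Unless a smaller set of genes or arrays explains a move, the cause was not tested.

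With an estimated correlation between genes, the lists that passed fell from 29 to 0 in cortex and from 59 to 2 in liver, the cell cycle list at 24 and 48 h after 18 mg/kg.

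Quantile normalisation gave 32 probe sets in cortex at 48 h after 18 mg/kg (0 before), 0 for the cortex dose difference (1), 1671 in liver at 48 h after 3 mg/kg (2898; 960 higher and 711 lower), 1 between the liver 0 h arms (0) and 0 for the liver dose difference (3). Centring of medians gave 12 in cortex at 24 h after 3 mg/kg (23), 23 at 48 h after 18 mg/kg (0), 0 for the cortex dose difference, 4 in liver at 4 h after 18 mg/kg (8) and 1 for the liver dose difference; in liver at 48 h after 3 mg/kg it gave 2882, with 2320 higher and 562 lower.

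Only brighter probe sets gave 41 in cortex at 24 h after 3 mg/kg, 29 at 48 h after 18 mg/kg and 25 for the tissue difference after 18 mg/kg (40). A variance trend with robust moderation gave 2 in cortex at 48 h after 18 mg/kg and 6 for the liver dose difference. The replicate block gave 1 in cortex at 4 h and 9 at 24 h after 3 mg/kg, 0 for the cortex dose difference, 17 in liver at 48 h after 18 mg/kg (30) and 1 for the liver dose difference. With 1 probe set per gene there were 48 in cortex at 24 h after 3 mg/kg, 33 at 48 h after 18 mg/kg, 1487 in liver at 48 h after 3 mg/kg (1212 higher and 275 lower), 5 at 4 h after 18 mg/kg and 0 for the liver dose difference.

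Fits on only the 6 arrays compared gave 15 and 3 in cortex at 24 and 48 h after 3 mg/kg, 1 and 1 at 4 and 24 h after 18 mg/kg and 1 between the 0 h arms. In liver they gave 0 at 4 h and 0 at 48 h after 3 mg/kg and 0 at 4 h after 18 mg/kg, with fewer arrays to estimate the spread. The pooled 0 h control gave 1 and 0 in cortex at 4 and 24 h after 3 mg/kg and 4 at 48 h after 18 mg/kg; in liver it gave 0 at 48 h after 3 mg/kg and 55, 4 and 57 at 4, 24 and 48 h after 18 mg/kg. The doses compared as 18 mg minus 3 mg without 0 h gave 3842 in cortex and 40 in liver.

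The gap covariate gave 0 for the cortex dose difference, and the oxidative phosphorylation list at 48 h after 18 mg/kg turned upward with adjusted p = 0.46. The gap and liver transcript covariates gave 11 in cortex at 24 h after 3 mg/kg, 0 for the dose difference and adjusted p = 0.75 for that list, again upward. The limit on the gap kept only replicate 3 of the 3 mg/kg 0 h group. At 48 h after 18 mg/kg it kept only replicate 2, with a hepatocyte mean of 11.57. The limit on liver transcripts kept only replicate 1 there, with an actin gap of 4.61. Counts below that use these groups, the dose difference included, rest on a single array in a group. They cannot show whether calls depended on RNA integrity or liver transcripts. Only arrays with a gap of at most 3 gave 1, 7 and 2 in cortex at 4, 24 and 48 h after 3 mg/kg, 1767 at 48 h after 18 mg/kg and 1 between the 0 h arms. Only arrays with few liver transcripts gave 1, 671 and 1 at 4, 24 and 48 h after 3 mg/kg, 1289, 1034 and 1751 after 18 mg/kg, 10 between the 0 h arms and 4098 for the dose difference.

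Without the 2 compressed arrays liver gave 1372 at 48 h after 3 mg/kg, 14 at 4 h and 55 at 48 h after 18 mg/kg, and the tissue difference 225 after 3 mg/kg and 79 after 18 mg/kg. With the gap covariate as well, liver gave 0 at 48 h after 3 mg/kg, 48 at 48 h after 18 mg/kg, 0 for the dose difference and 31 passing lists. At 48 h after 3 mg/kg Srxn1 was then at -0.13 and Ghr at -0.02, and the growth hormone list turned downward at 24 and 48 h (adjusted p = 0.6 and 0.65).

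Leaving out 1 array in turn gave, in cortex, 0 to 33, 0 to 125 and 0 to 4 at 4, 24 and 48 h after 3 mg/kg, and 0 to 2 and 0 to 2146 at 24 and 48 h after 18 mg/kg. In liver it gave 0 to 1809, 0 to 3777 and 0 to 7764 after 3 mg/kg, 0 to 33 and 5 to 21 at 4 and 48 h after 18 mg/kg, 0 to 4123 between the 0 h arms and 37 to 65 passing lists. Leaving out all arrays of 1 replicate number gave 0 to 2531 for the dose difference in cortex and 0 to 1 in liver, and 0 to 345 and 3 to 8 for the tissue difference after 3 and 18 mg/kg.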

Other observations

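The test of the clock genes in this part was chosen after the results were seen; the gene lists were written before the data were examined.

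Genes of the growth hormone and sex pattern of liver lay above 0 at all later times after 3 mg/kg, with 16 of 17 measured above 0 each time and medians of 0.71, 0.74 and 0.83 (camera adjusted p = 0.017, 0.0063 and 0.015, and adjusted p = 0.83 with an estimated correlation for each). These values rest on the compressed 3 mg/kg 0 h replicate 2, without which the list missed the threshold at every time (adjusted p = 0.58, 0.17 and 0.17). With the 3' minus 5' gap as a covariate and without the compressed arrays it turned downward at 24 and 48 h (adjusted p = 0.6 and 0.65), and Ghr was at -0.02 at 48 h. At 48 h 4 of them rose: Cyp2c7 (log2 1.57 ± 0.45 SE, n = 3 per group) and Cyp2c11 (0.99 ± 0.31), steroid hydroxylases, Ghr, the growth hormone receptor (1.24 ± 0.33), and Rgn, a calcium-binding protein (0.99 ± 0.29). After 18 mg/kg the medians were -0.05, 0.084 and 0.04, and the list did not pass. Chaperone genes in liver were lower as a group at 4 h after 18 mg/kg, with 14 of 15 below 0 and a median of -0.64 (camera adjusted p = 0.00061, and adjusted p = 0.83 with an estimated correlation), and 0 passed when adjusted over the list alone. That group holds a compressed array, and the actin gap changed by -1.09. The list passed camera whichever array of the comparison was left out (adjusted p at most 0.02).

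Microglia genes in cortex, 16 measured, did not pass as a list, and 11 member calls were made over the 6 contrasts when adjusted over the list alone. Tyrobp and C1qc are given here. Their values had opposite signs in the 2 arms, as probe sets in general did (r = -0.409 at 48 h across probe sets), and the actin gap fell by 0.549 at 48 h after 3 mg/kg and rose by 1.33 after 18 mg/kg. Tyrobp, a microglial signalling adaptor, was at 0.38 ± 0.08 SE at 24 h and 0.32 ± 0.08 at 48 h after 3 mg/kg, and at -0.32 ± 0.08 at 48 h after 18 mg/kg (n = 3 per group; adjusted p = 0.075, 0.28 and 0.1). C1qc, a complement component, was at 0.36 ± 0.11, 0.35 ± 0.11 and -0.53 ± 0.11 in the same comparisons. C1qc after 3 mg/kg and Tyrobp after 18 mg/kg were chosen after their values were seen.

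With 3 arrays per group only 10 splits of 6 arrays exist, too few for a share under 0.05. The real split stood alone, 1 of 10, in cortex at 24 h after 3 mg/kg (23; highest other 0), in liver at 4 and 48 h after 3 mg/kg (7 and 2898; highest other 0 for both) and in liver at 4 and 48 h after 18 mg/kg (8 and 30; highest other 0 for both). In the other comparisons the real count was 0, so all 10 splits gave as many. The highest other count was 0 in cortex at 4 and 48 h after 3 mg/kg and 4 h after 18 mg/kg and in liver at 24 h after 18 mg/kg. It was 3926 and 4363 in cortex at 24 and 48 h after 18 mg/kg, 3818 between the cortex 0 h arms, 616 in liver at 24 h after 3 mg/kg and 17 between the liver 0 h arms. Splits that call many probe sets where the real groups give 0 point to a structure of the samples other than the groups. In cortex these were comparisons in which both groups held arrays on either side of an actin gap of 3. Where the highest other count in cortex was 0, the later group lay wholly on one side of it. Which split gave each highest count was not recorded, so whether it divided the arrays by the gap was not tested.

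The changes of the clock genes in liver at 4 h correlated between the doses, with r = 0.927 over 17 genes. Of 10000 random lists of that size 0% gave an r as high. Across all probe sets these changes correlated at r = -0.291 between the doses. Random lists thus came from a background of negative correlation, which made a high r in them less likely. A hypothesis is that tissue at 4 h was taken at another time of day than at 0 h, which could shift clock genes without any effect of RDX. If so, they should return at 24 and 48 h. The median absolute change at 4, 24 and 48 h was 0.62, 0.3 and 0.2 after 18 mg/kg and 0.34, 0.31 and 0.32 after 3 mg/kg. At 48 h it was thus 0.33 and 0.96 of that at 4 h, so the test could not decide. The 0.96 is a median over all 17 genes, against 0 h arrays that include the compressed replicate 2. At 48 h after 3 mg/kg Nr1d1 was at 5.56 to 7 against 5.48 to 6.41 at 0 h. Cry1 was at 8.71 to 9.38 against 9.03 to 9.32 and Per3 at 5.55 to 5.87 against 5.96 to 6.58, while Bmal1 was higher by log2 2.14. A return would also follow if an effect of RDX had passed by then. In cortex the doses correlated at 0.32 over the 17 genes. A vehicle group at each time, or recorded clock times, would separate time of day from dose.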
